A study of Mus musculus with 9 samples.

How the data were processed

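RNA sequencing counts of 9 libraries of mouse mesenchymal stem cells were used, 3 libraries in each of 3 groups that differ in siRNA and inhibitor. Per the submitters' processing notes, bcl2fastq, TopHat2 2.0.6 and HTSeq were used with the mm10 build; their order and the gene annotation are not given in the sources used here. The deposited table holds a raw count per gene and library, and the authors' RPKM, which divides the count by a coding length and by a library total. Per the file headers, the coding length is in bases and the gene positions are on mm10 (GRCm38). Only 37.8% of these lengths were multiples of 3, so the term, kept here, does not mean coding sequence alone. The RPKM values were used only to recover each library total; the summed counts came to 89.8 to 90.7% of it. All counts were even, with 0 odd values in the 9 columns, as if both mates of a read pair had been counted. The table has 23358 entries, of which 69 share 26 names. Of its symbols, 20973 occur in GENCODE M21, and 20834 of these (99.3%) overlap the gene of that name on the same chromosome. Gene positions printed here come from GENCODE M21. Another 6 columns of per-sample values, for a combination treatment, and the H3K27me3 ChIP-seq part, with 1 replicate per group, were not used here.

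Groups followed the sample titles. Tests were run in R 4.3.3 with edgeR 4.0.16: filterByExpr by group (minimum count 10, minimum total 15), TMM scaling, a quasi-likelihood fit with robust estimation over all 9 libraries, and F-tests of the 3 comparisons between groups, without a replicate block. This left 13240 genes tested and 10118 filtered out. The common biological coefficient of variation was 8.12%, with 6 residual degrees of freedom and a median prior of 6.61. P values were adjusted by Benjamini-Hochberg over all genes of a comparison, with a threshold of 0.05. Log2 fold changes are given with their standard error (SE), and levels as CPM after TMM scaling, with the standard deviation (SD), n = 3 libraries per group. Log2 CPM per library used a prior count of 2. Libraries were also compared by principal components. Other analyses and the figures used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

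Before the data were examined, 24 gene lists were fixed: osteoblast, adipocyte, chondrocyte and stromal progenitor markers, Wnt targets, cadherins and catenins, the Polycomb complexes PRC2 and PRC1 (the latter with H3K27 demethylases), Hox genes, other developmental transcription factors, cell cycle, Cdk inhibitors with p53 targets and senescence genes, cholesterol synthesis, interferon response with antigen presentation, extracellular matrix, contractile genes, Yap targets, BMP and TGF-beta signalling, stress responses, imprinted genes, and markers of macrophages and other haematopoietic cells, of endothelium, of skeletal muscle and of neural cells. Ctnnb1 is in no list. Each list was tested against the other genes with camera from limma 3.58.1, at a preset inter-gene correlation of 0.01 and adjusted over the lists of a comparison; camera with an estimated correlation and fry were alternatives. With an estimated correlation, camera also refers to the residual degrees of freedom, so its p values can rise even where that correlation is low. Ranges over alternatives printed for a list cover camera, not fry, which tests a list without the other genes. Member counts are given over all genes tested and adjusted over the list alone.

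The genes named were set by a rule, also fixed before the data were examined. Ctnnb1, Ezh2 and Ezh1 came first. For each treatment against siCTL, the 10 highest and 10 lowest log2 fold changes were taken among genes past the threshold, with a mean of at least 2 CPM and no overlap between the libraries of both groups; for siBcat against GSK126, the 5 highest and 5 lowest. Each list gave up to 4 members with the smallest adjusted p, and the overlap of both treatments up to 5 genes per class. Predicted genes were left out of the highest, lowest and overlap classes. Genes named outside this rule are marked as such where they appear.

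Alternatives were other scalings (DESeq2 size factors, upper quartile, library size only), no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, only the 2 groups compared, robust estimation off, a replicate block, each library left out in turn and a fold change of at least 2. Halved counts and a removed trend on coding length or GC content (loess, span 0.5) were added after the data were seen; GC content was at hand for 90.4% of the genes tested. Overlaps between both treatments were set beside groups simulated without a change against the same controls, in 50 draws. The 10 splits of each pair of groups were also tested.

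The procedure was tested on simulated counts with 50 genes changed at each of 4 sizes, for 13240 genes. The changed genes had a mean of at least 1 CPM and were in no list, so the shares below do not cover lower genes. In the comparison of siBcat with siCTL, 36% of changes by 25% were recovered, 88% of 1.5-fold, 96% of 2-fold and 100% of 4-fold, with 14 false calls among 174 (8%). For GSK126 the shares were 34, 84, 94 and 98%, with 12 false calls among 180 (6.7%). There the cell cycle list was also raised by 25%, and its calls are part of the 180. The even counts double the counting scale, so a count of 0 was taken to allow up to 6 counts, or 3 fragments; this floor, 0.107 to 0.142 CPM by library, covers counting error only.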

Results

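RNA was sequenced from 9 cultures of mesenchymal stem cells, multipotent stromal cells from the marrow of adult C57BL/6 mice at passages 4 to 10. There were 3 groups of 3 biological replicates. Control cultures (siCTL) received a non-targeting siRNA, and a second group (GSK126) the same siRNA with 5 µM GSK126, an inhibitor of the H3K27 methyltransferase Ezh2. The third group (siBcat) received siRNA against beta-catenin, the Ctnnb1 product, which joins cadherins to the cytoskeleton and carries Wnt signals to the nucleus. Sample titles, source names, the series text and count column names give siBcat no inhibitor, whereas its treatment label lists 5 µM GSK126. The groups used here follow the titles. Cells were grown in osteogenic medium and lysed on day 4. Summed counts were 44506814, 45683906 and 46516898 in siCTL, 55898774, 43062026 and 49142018 in GSK126, and 42324200, 50327938 and 46848998 in siBcat. All counts were even, so each fragment may have been counted as 2.

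Ctnnb1 (chromosome 9, 120929216 to 120960507) stood at 854.4, 860.1 and 878.9 CPM in siCTL, at 925.4, 949.7 and 905.9 CPM in GSK126, and at 19.33, 19.31 and 19.13 CPM in siBcat. It was 44.9-fold lower in siBcat than in siCTL (log2 fold change -5.49, SE 0.05, adjusted p = 1.13e-15). In GSK126 it differed from siCTL by 0.10 (SE 0.04, adjusted p = 0.109), a difference past the threshold without GSK126 replicate 3 (0.00763) and with library size only (0.0465), over alternatives from 0.00763 to 0.305. Ezh2 (chromosome 6, 47530139 to 47595341) had means of 23.7 ± 0.623, 27.85 ± 1.72 and 27.46 ± 0.447 CPM (SD, n = 3) in siCTL, GSK126 and siBcat. It was higher by 0.23 (SE 0.06, adjusted p = 0.0169) with GSK126 and by 0.21 (SE 0.06, adjusted p = 0.0195) with siBcat. Neither call held when 1 library was left out: for GSK126 it ended without GSK126 replicate 1 (0.0751) or siCTL replicate 1 or 2 (0.0662 and 0.0681), over alternatives from 0.0109 to 0.0751. For siBcat it ended without siBcat replicate 1, 2 or 3 (0.0563, 0.0524 and 0.0722) or siCTL replicate 1 or 2 (0.0696 and 0.0749), over alternatives from 0.0051 to 0.0749. Ezh1, the second H3K27 methyltransferase (chromosome 11, 101191115 to 101226463), was 1.39-fold lower in siBcat (log2 fold change -0.47, SE 0.07, adjusted p = 0.000338) and differed by -0.10 (SE 0.07, adjusted p = 0.340) in GSK126.

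**Figure D1:**
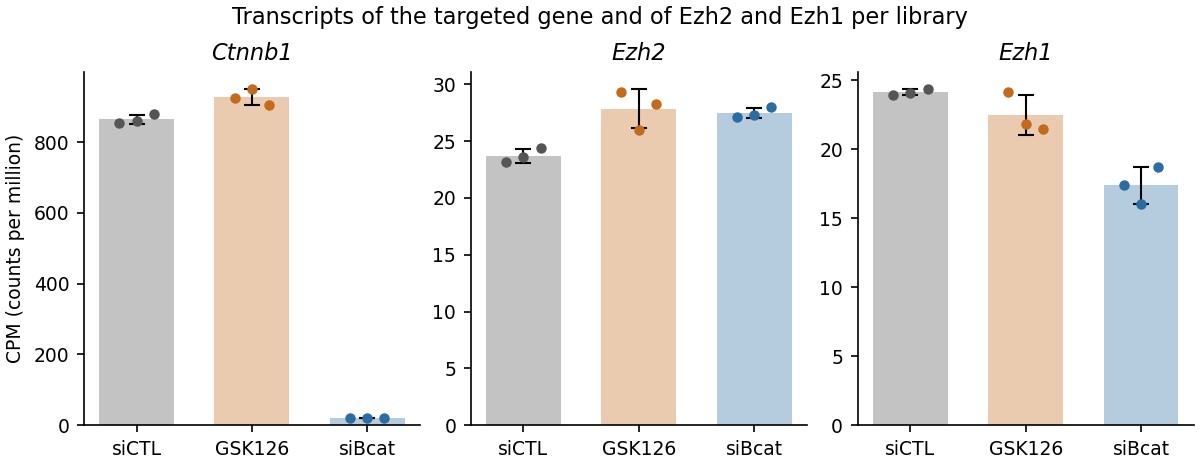
Levels of Ctnnb1, Ezh2 and Ezh1 in CPM (vertical axes from 0) in each of the 9 libraries (points), with the group mean (bar) and SD (error bar, n = 3). Ctnnb1 stood at 19.26 CPM in siBcat, against 864.5 CPM in siCTL.

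The 3 groups separated on the principal components, with siBcat at 34.77 to 36.85 on the first (43.6% of the variance), against -9.35 to -7.12 for siCTL and -27.94 to -26.68 for GSK126. The third (7.6%) set GSK126 replicate 3 apart, at 24.75. In that library, deviations from the group mean ran with coding length: the median was 0.18 (log2) in the shortest of 10 equal bins of genes and -0.23 in the longest, and a trend on length took up 42% of their variance. In siCTL and siBcat libraries such a trend took up 0.1 to 2.4%. A trend on GC content took up 20.7% in siCTL replicate 1 and 31.6% in siCTL replicate 3, against 5.9% in GSK126 replicate 3.

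**Figure D2:**
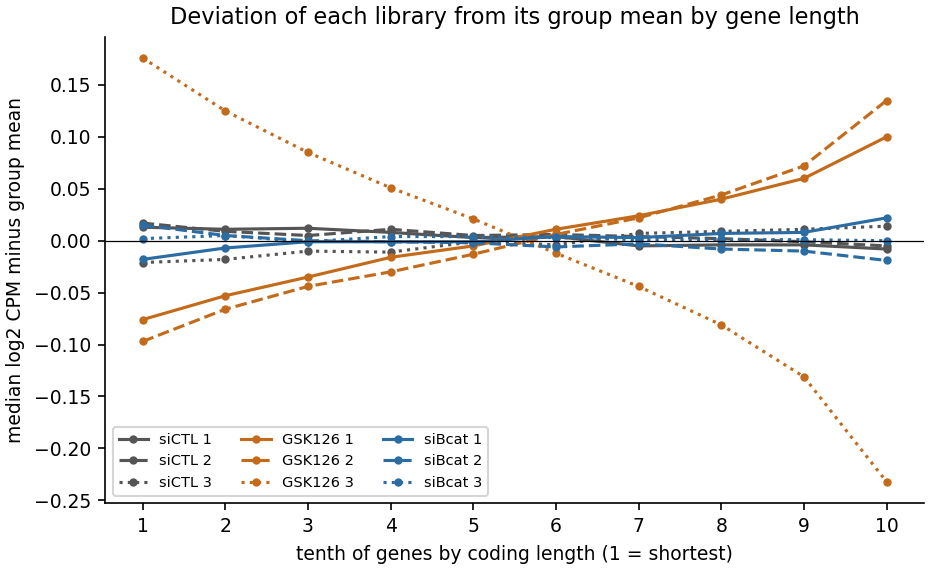
Median deviation of each library from its group mean (log2 CPM, vertical axis) in 10 equal bins of the tested genes by coding length, from the shortest to the longest (horizontal axis); colours are groups and line styles replicates. GSK126 replicate 3 runs from 0.18 to -0.23, and its 2 group mates run the other way because they share its mean.

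The comparison of siBcat with siCTL asks which transcripts change when beta-catenin is depleted. Among genes with a mean of at least 2 CPM and no overlap between groups, interferon-response genes were the largest group of the highest changes. Usp18, a protease that removes Isg15 from proteins, was 23.9-fold higher (log2 fold change 4.58, SE 0.55, adjusted p = 0.000188; chromosome 6, 121245906 to 121270917), from 0.290 ± 0.124 to 7.08 ± 4.67 CPM (SD, n = 3). Ifit1, which binds foreign RNA, was 10.1-fold higher (3.33, SE 0.46), and Isg15, a ubiquitin-like modifier, 14.8-fold (3.89, SE 0.61). The other highest changes within these limits were Ifi44 (3.85), Oasl2 (3.12), Bcan (2.72), Rtp4 (2.67), Xaf1 (2.65), Dhx58 (2.60) and the skeletal muscle actin Acta1 (2.56, SE 0.11), at 1.77 CPM in siCTL and 10.4 CPM in siBcat. Next to Ctnnb1, the lowest were Sparcl1 (-3.91), which at 0.140 CPM in siBcat was about at the floor, the esterase gene Iah1 (-2.89), the Wnt antagonist Dkk2 (-2.85, SE 0.13), Hopx (-2.82), the Wnt ligand Wnt5b (-2.73, SE 0.14), Magel2 (-2.55), Ccdc3 (-2.37), Card10 (-2.31) and Lbp (-2.30). Iah1 was 7.42-fold lower, from 45.99 ± 1.82 to 6.21 ± 0.383 CPM. By the rule for naming them, all 3 siBcat libraries lay on one side of all 3 siCTL libraries for each of these genes.

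Of 32 interferon-response and antigen-presentation genes tested, 26 rose and 1, Ifit2 (-0.47), fell, with the same counts adjusted over the list alone. Tap1, which carries peptides to class I molecules, rose by 0.76 (SE 0.07), the class I gene H2-D1 by 0.48 (SE 0.07) and the interferon regulatory factor Irf9 by 1.16 (SE 0.16). Camera gave an adjusted p of 1.95e-08 for the list, and 0.34 with an estimated correlation, the highest of its alternatives (lowest 1.56e-15). The list mean over siCTL was 1.86 (log2) in siBcat replicate 1, and 1.02 and 1.07 in replicates 2 and 3. Without siBcat replicate 1, 21 of the 26 members were still past the threshold. Of the 8 macrophage and haematopoietic markers tested, 2 rose, Lyz2 and Cd74, and 1, Cd68, fell (2 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.806). All 3 stayed under 2 CPM in every group mean. Cd74 was no longer past the threshold without siCTL replicate 2 or 3 or siBcat replicate 2 or 3 (0.106, 0.0742, 0.0714 and 0.1; alternatives 0.0199 to 0.106). Cd68 was not past it without siBcat replicate 1 or 3 or siCTL replicate 3 (0.118, 0.0764 and 0.154; alternatives 0.0206 to 0.154).

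Contractile genes were higher with siBcat, with 10 of 16 members rising and 1, Smtn, falling (the same adjusted over the list alone). The smooth muscle actins Actg2 and Acta2 rose by 1.51 (SE 0.06) and 0.87 (SE 0.06), Tagln by 1.14 (SE 0.09) and the myosin light chain Myl9 by 0.61 (SE 0.07). Acta2 went from 1157 to 2118 CPM. The camera adjusted p was 5.98e-06, and 0.0716 with an estimated correlation (alternatives 1.15e-07 to 0.0716). Cholesterol synthesis genes followed the same direction, with 17 of 25 rising and 1 falling (17 and 1 adjusted over the list alone). Hsd17b7 (0.80, SE 0.07), Cyp51 (0.48, SE 0.04) and Sc5d (0.52, SE 0.05), enzymes of the pathway, were examples. The adjusted p was 3.94e-05, and 0.0539 with an estimated correlation (alternatives 3.96e-06 to 0.0539). Stress-response genes numbered 11 higher and 1 lower, Herpud1, of 20 (the same adjusted over the list alone). Asns, which makes asparagine, rose by 1.29 (SE 0.07), Trib3 by 1.08 (SE 0.13), and the serine pathway genes Phgdh and Shmt2 by 0.56 (SE 0.07) and 0.53 (SE 0.06). The adjusted p was 0.000125, and 0.0781 with an estimated correlation (alternatives 1.1e-05 to 0.0781).

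Among 38 cell cycle genes, 14 rose and 3 fell (16 and 4 adjusted over the list alone). Those rising included the ribonucleotide reductase subunit Rrm2 (0.70, SE 0.05), the cyclin gene Ccne1 (0.64, SE 0.07), the replication helicase gene Mcm5 (0.36, SE 0.05) and the mitotic kinase gene Aurka (0.40, SE 0.07). The 3 that fell were Cenpf, E2f1 and Foxm1. Camera gave an adjusted p of 0.0418, which was 0.146 with an estimated correlation and 0.0577 with library size only (alternatives 0.017 to 0.146). Cdk inhibitors, p53 targets and senescence genes numbered 9 higher and 4 lower of 21 (10 and 4 adjusted over the list alone), with Ccng1 (0.72, SE 0.06), the Cdk inhibitor Cdkn1a (0.62, SE 0.05) and the p53 regulator Mdm2 (0.41, SE 0.05) rising. The adjusted p was 0.0418, and 0.179 with an estimated correlation. It was 0.0528 without GSK126 replicate 1 and 0.0657 without GSK126 replicate 3, libraries that enter this comparison through the shared estimate of spread (alternatives 0.0212 to 0.179). Of 6 skeletal muscle genes, 1 rose, Acta1 (adjusted p of the list 0.0158; 0.182 without GSK126 replicate 3 and 0.179 with an estimated correlation; alternatives 0.00243 to 0.214).

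Adipocyte genes were lower, with 11 of 24 falling and 4 rising (11 and 4 adjusted over the list alone). The fatty acid binding proteins Fabp4 and Fabp5 fell by 1.18 (SE 0.09) and 0.52 (SE 0.06) on the log2 scale, the lipase gene Lpl by 0.63 (SE 0.05) and the adipokine gene Adipoq by 1.60 (SE 0.18). The 4 that rose were Cebpb, Cebpd, Pparg and Slc2a4. Its adjusted p was 0.0434, and 0.168 with an estimated correlation. The call ended without siBcat replicate 1 or 2 (0.0675 and 0.0511) or siCTL replicate 1 or 2 (0.0525 and 0.0716), over alternatives from 0.0212 to 0.168. Osteoblast genes went both ways, with 6 rising and 5 falling of 20 (6 and 6 adjusted over the list alone). The matrix protein gene Spp1 rose by 0.54 (SE 0.06), from 12130 to 17610 CPM, Tnfrsf11b, a decoy receptor that restrains osteoclasts, by 0.76 (SE 0.06), and Dlx3 by 1.49 (SE 0.12). Phex, of phosphate regulation, fell by 1.42 (SE 0.10), and outside the naming rule the transcription factor Runx2 fell by 0.30 (SE 0.08). The list's test pointed up (adjusted p = 0.836), although its median was -0.14 and its mean -0.09.

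Wnt targets likewise split, with 5 rising and 5 falling of 17 (5 and 7 adjusted over the list alone). Wisp2, a secreted matricellular protein, rose by 2.04 (SE 0.07), from 124.6 to 510.6 CPM, the hyaluronan receptor Cd44 by 0.85 (SE 0.06), and Tnfrsf11b and Myc by 0.76 (SE 0.06) and 0.68 (SE 0.08); Wisp1, the last riser, was at 0.48. The 5 that fell, named after their values were seen, were the Wnt transcription factor genes Lef1 (-0.41, SE 0.08) and Tcf7 (-0.94, SE 0.18), the Wnt inhibitors Apcdd1 (-1.30, SE 0.23) and Notum (-1.05, SE 0.37), and the receptor ligase gene Rnf43, at 0.191 CPM in siCTL and 0.0135 CPM in siBcat. The test pointed up (adjusted p = 0.0576) while the median was -0.04 and the mean -0.28. It passed the threshold with halved counts (0.0142), the length or GC trend removed (0.019 and 0.0491), a filter of 1 CPM (0.0295) or only the 2 groups compared (0.0299), over alternatives from 0.0142 to 0.715. Axin2, a common Wnt target, had 0 to 8 counts per library and was filtered out. Of 12 cadherin and catenin genes, 5 rose and 3 fell (the same adjusted over the list alone; adjusted p = 0.825). Jup, or plakoglobin, the closest relative of beta-catenin, fell by 1.12 (SE 0.08) and Cdh11 by 0.51 (SE 0.06), while Cdh2 rose by 0.31 (SE 0.06). That test pointed down, as did the mean of -0.06, with a median of 0.04.

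Stromal progenitor genes numbered 3 higher and 5 lower of 15 (4 and 5 adjusted over the list alone; adjusted p = 0.0576; alternatives 0.0394, without a filter, to 0.458). The stem cell niche factors Cxcl12 and Kitl fell by 0.65 (SE 0.05) and 1.06 (SE 0.08), the adhesion molecule gene Vcam1 by 0.79 (SE 0.05) and Nes by 1.25 (SE 0.07). Of 21 Hox genes, 2 rose and 6 fell (2 and 9 adjusted over the list alone), with Hoxa10 (-0.81, SE 0.05), Hoxa13 (-0.91, SE 0.09) and Hoxa11 (-0.65, SE 0.07) among the lower. The Hox adjusted p of 0.0576 passed the threshold without siCTL replicate 3 (0.0405) or siBcat replicate 2 (0.0458), over alternatives from 0.0405 to 0.179. PRC2 genes numbered 2 higher and 5 lower of 12 (the same adjusted over the list alone; adjusted p = 0.474), with Mtf2 (-0.41, SE 0.07) and Rbbp4 (-0.30, SE 0.06) falling. PRC1 and demethylase genes numbered 2 and 5 of 18 (the same adjusted over the list alone), with the chromobox genes Cbx7 (-1.92, SE 0.16) and Cbx6 (-0.71, SE 0.06) falling; the adjusted p of 0.136 was 0.0468 without siCTL replicate 3 (alternatives 0.0468 to 0.458). Other developmental transcription factors numbered 9 and 7 of 42 (10 and 7 adjusted over the list alone; adjusted p = 0.15), with Onecut2 (1.16, SE 0.11), Irx3 (1.44, SE 0.16) and Msx1 (1.78, SE 0.26) rising.

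Matrix genes changed in both directions, with 14 rising and 12 falling of 35 (15 and 13 adjusted over the list alone). The adhesion-modulating protein gene Tnc rose by 1.97 (SE 0.10), from 289 to 1135 CPM, and the collagenase gene Mmp13 by 1.06 (SE 0.07), while the small proteoglycan gene Ogn fell by 1.47 (SE 0.06) and Fbln1 by 1.62 (SE 0.07). Their test (adjusted p = 0.836) and median (0.08) pointed up and their mean (-0.02) down. Chondrocyte genes numbered 1 higher and 3 lower of 10 (the same adjusted over the list alone; adjusted p = 0.825): the cartilage collagen gene Col2a1 rose by 1.87 (SE 0.13), and Col10a1, of hypertrophic cartilage, fell by 1.15 (SE 0.08). Of 15 imprinted genes, 3 rose and 4 fell (the same adjusted over the list alone; adjusted p = 0.578), with Impact at 0.84 (SE 0.05) and Peg10 at -0.84 (SE 0.13). Yap targets numbered 2 and 1 of 14 (1 and 1 adjusted over the list alone; adjusted p = 0.836), with Ankrd1 at -1.81 (SE 0.14); the test and the mean of -0.07 pointed down and the median of 0.05 up. The risers were Cyr61 and Lats2, and neither was past the threshold without siCTL replicate 2 (0.0516 and 0.117) or siBcat replicate 2 (0.0546 and 0.114); alternatives ran from 1.98e-05 to 0.0546 for Cyr61 and from 0.000309 to 0.187, without siCTL replicate 3, for Lats2. BMP and TGF-beta genes numbered 2 and 3 of 17 (the same adjusted over the list alone; adjusted p = 0.836), among them the inhibitor gene Id4 (1.71, SE 0.26) and the BMP antagonist gene Chrd (-0.61, SE 0.11). The other riser, Id3, was not past the threshold without siBcat replicate 1 or 2 or GSK126 replicate 3 (0.0734, 0.0947 and 0.0764; alternatives 0.00275 to 0.116). In the endothelial list 1 gene, Kdr (1.52, SE 0.33), rose and 1 fell of 3 (adjusted p = 0.708), and in the neural list 1 rose and 1 fell of 5 (adjusted p = 0.877), the same adjusted over each list alone. The endothelial gene that fell, Vwf, was not past the threshold without siCTL replicate 2 or 3 or siBcat replicate 1 or 2 (0.097, 0.0945, 0.0868 and 0.114; alternatives 0.0154 to 0.114). The neural genes Tubb3, higher, and S100b, lower, were not past it without siCTL replicate 3 (0.0604 and 0.0962) or siBcat replicate 3 (0.0559 and 0.0703), nor S100b without siBcat replicate 1 (0.0693); alternatives ran from 0.00358 to 0.0604 and from 0.00989 to 0.0962.

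Across the 13240 genes tested, 2346 were higher and 2320 lower in siBcat than in siCTL (35.2% of those tested), with 265 and 338 at a fold change of at least 2. The libraries of both groups did not overlap for 55.2% of the genes, against 10% by chance for 3 against 3. Of the calls 50.3% were higher, a share of 41.7% with library size only and of 55.4% with the length trend removed, so which direction held more genes turned with the scaling. Without GSK126 replicate 3 the counts were 3202 and 3118. No list call of this comparison held with an estimated correlation. That estimate lay below the preset 0.01 for cholesterol synthesis (-0.024), cell cycle (-0.012) and adipocyte genes (-0.008). Correlation among members was thus not what ended those calls. For the other lists called it lay above 0.01, up to 0.527 for interferon and antigen-presentation genes.

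The comparison of GSK126 with siCTL asks which transcripts change when Ezh2 is inhibited. Among genes with a mean of at least 2 CPM and no overlap between groups, genes of fat cells showed the largest rises. Cd36, a fatty acid transporter (chromosome 5, 17781690 to 17888801), was 41.5-fold higher (log2 fold change 5.38, SE 0.29, adjusted p = 1.17e-07), from 0.220 ± 0.0771 to 9.21 ± 1.38 CPM (SD, n = 3). The lipid droplet coat gene Plin1 (chromosome 7, 79720218 to 79732903) was 22.3-fold higher (4.48, SE 0.21), and the adipokine gene Adipoq 8.11-fold (3.02, SE 0.14), from 3.15 ± 0.581 to 25.6 ± 2.62 CPM. The other highest were Car3 (3.17), the imprinted gene Mest (3.00, SE 0.10), Steap4 (2.89), Col2a1 (2.34), Aldh1a7 (2.28), G0s2 (2.25), an inhibitor of the lipase Pnpla2, and Slc2a6 (2.23). Decreases were smaller. The lowest within these limits was Pi15 (chromosome 1, 17601901 to 17630939), 3.89-fold lower (-1.96, SE 0.12), from 112.5 ± 6.74 to 28.9 ± 5.74 CPM. It was followed by Gdap1 (-1.75), Ptpn5 (-1.73), Susd2 (-1.71), Neb (-1.65), Evi2a (-1.54), Fam131b (-1.50), Mrgprf (-1.49), Gchfr (-1.40) and Macc1 (-1.30).

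All 38 cell cycle genes rose with GSK126, over all genes and adjusted over the list alone. Rrm2, which makes deoxynucleotides, rose by 1.10 (SE 0.05), from 95.8 to 206.1 CPM, the helicase genes Mcm3 and Mcm5 by 0.89 (SE 0.05) and 0.73 (SE 0.05), and the cyclin gene Ccna2 by 0.84 (SE 0.06). The list mean over siCTL was 0.65, 0.65 and 0.66 (log2) in replicates 1 to 3. Camera gave an adjusted p of 4.35e-44, and 7.26e-05 with an estimated correlation (alternatives 2.91e-51 to 7.26e-05). Without GSK126 replicate 3, the library with the length trend, 37 of 38 were past the threshold. Adipocyte genes numbered 19 higher and 0 lower of 24 (20 and 1 adjusted over the list alone), with the desaturase gene Scd1 (1.24, SE 0.07) rising from 573.3 to 1354 CPM besides Adipoq, Plin1 and Cd36. The list mean over siCTL was 1.42, 1.44 and 1.41 in replicates 1 to 3, and the adjusted p was 3.57e-37, and 8.48e-05 with an estimated correlation (alternatives 1.05e-46 to 8.48e-05). Cholesterol synthesis genes numbered 24 higher and 0 lower of 25 (25 and 0 adjusted over the list alone). Fdps (0.60, SE 0.07), an enzyme of the pathway, Hmgcs1 (0.44, SE 0.05), near its start, and its sensor gene Insig1 (0.49, SE 0.05) were among them (adjusted p = 1.21e-14, and 0.000902 with an estimated correlation; alternatives 9.59e-19 to 0.000902).

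**Figure D3:**
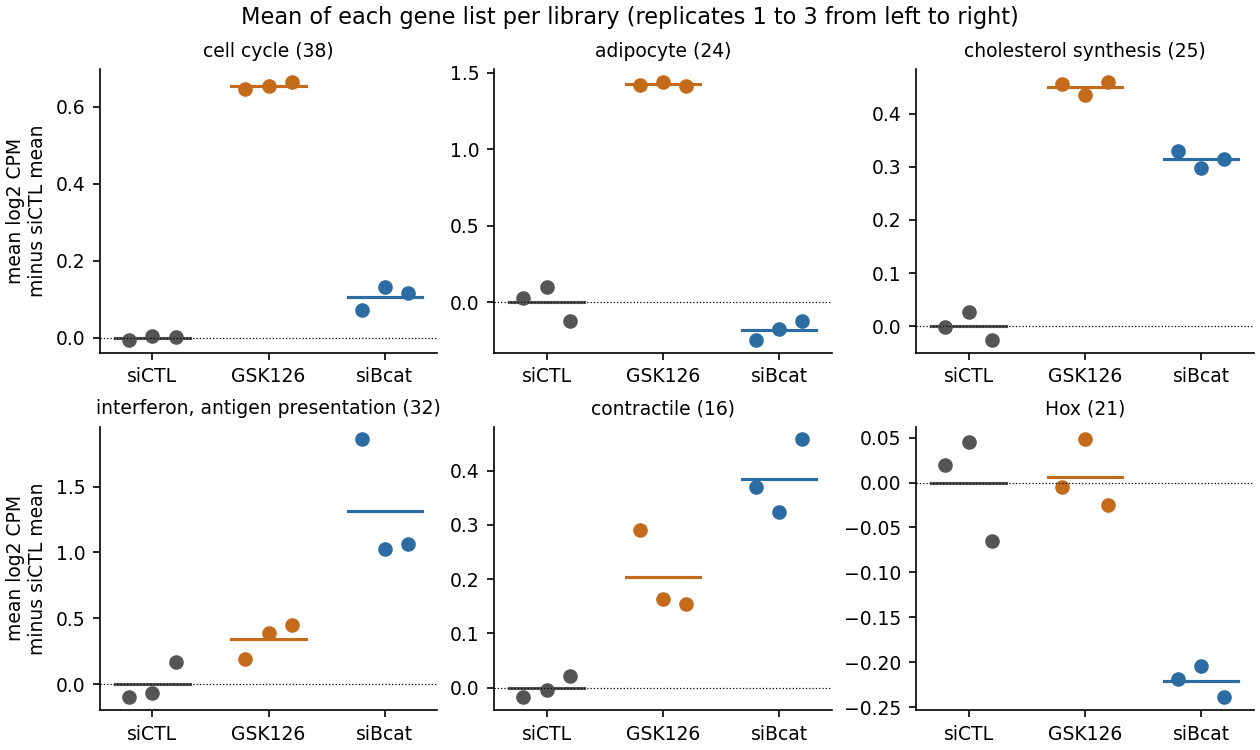
Mean of 6 gene lists in each of the 9 libraries (points), as log2 CPM minus the siCTL mean (vertical axes, each with its own range), with lines at group means; brackets give the genes per list. Cell cycle genes stood at 0.65 to 0.66 in GSK126 and at 0.07 to 0.13 in siBcat, and interferon genes at 1.86 in siBcat replicate 1 against 1.02 and 1.07 in replicates 2 and 3.

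Wnt targets numbered 8 higher and 0 lower of 17 (9 and 0 adjusted over the list alone). Nkd1 and Nkd2, feedback inhibitors of Wnt signalling, rose by 1.73 (SE 0.12) and 0.97 (SE 0.09), and Tnfrsf11b and Wisp2 by 0.94 (SE 0.06) and 0.63 (SE 0.07); camera gave an adjusted p of 4.29e-06, and 0.038 with an estimated correlation (alternatives 1.71e-06 to 0.038). Chondrocyte genes numbered 4 and 0 of 10 (the same adjusted over the list alone), with Col2a1 going from 19.4 to 98.3 CPM, Col10a1 rising by 1.49 (SE 0.08), Matn3 by 1.60 (SE 0.34) and the joint lubricant gene Prg4 by 0.57 (SE 0.11). Their adjusted p was 2.69e-05, and 0.119 with an estimated correlation (alternatives 7.37e-08 to 0.119). Osteoblast genes numbered 5 higher and 3 lower of 20 (6 and 3 adjusted over the list alone; adjusted p = 0.254). The growth factor gene Bmp2 rose by 2.48 (SE 0.27), from 0.351 to 1.98 CPM, and, outside the naming rule, the alkaline phosphatase gene Alpl by 0.54 (SE 0.10). Spp1 fell by 0.85 (SE 0.06), from 12130 to 6742 CPM, and Dmp1, a matrix protein of osteocytes, by 0.51 (SE 0.09). Stromal progenitor genes numbered 6 and 4 of 15 (6 and 5 adjusted over the list alone; adjusted p = 0.238), with Cxcl12 rising by 1.09 (SE 0.05), from 3750 to 8002 CPM, and the growth factor receptor genes Pdgfra and Pdgfrb at -0.59 (SE 0.07) and -0.36 (SE 0.07).

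Matrix genes numbered 9 higher and 11 lower of 35 (10 and 12 adjusted over the list alone). The collagen gene Col3a1 fell by 1.17 (SE 0.06), from 6329 to 2807 CPM, Col8a1 by 0.93 (SE 0.08) and Thbs2 by 0.83 (SE 0.07), and the elastic fibre gene Fbln5 rose by 0.84 (SE 0.07). The test (adjusted p = 0.0574) and the median of -0.06 pointed down and the mean of 0.05 up. It passed the threshold without siCTL replicate 3 (0.0312), GSK126 replicate 1 or 2 (0.0327 and 0.0286) or siBcat replicate 3 (0.0474), and with 8 other alternatives, among them the replicate block (0.047), upper-quartile scaling (0.0395) and the length trend removed (0.0313), over alternatives from 0.0106 to 0.557. Contractile genes numbered 6 and 1 of 16 (6 and 2 adjusted over the list alone), with Actg2 (0.83, SE 0.06), Tagln (0.79, SE 0.08), Myl9 (0.75, SE 0.07) and Acta2 (0.58, SE 0.06) rising. Their adjusted p was 0.00206, and 0.113 with an estimated correlation (alternatives 0.000333 to 0.113). BMP and TGF-beta genes numbered 8 and 3 of 17 (9 and 4 adjusted over the list alone), with the BMP target gene Id1 (1.76, SE 0.21) and the ligand gene Bmp4 (1.31, SE 0.08) rising and Tgfb3 (-0.36, SE 0.04) falling. The adjusted p of 0.0406 was 0.0889 without GSK126 replicate 2, 0.159 without replicate 3 and 0.428 with an estimated correlation (alternatives 0.0135 to 0.428). Yap targets numbered 6 and 2 of 14 (7 and 2 adjusted over the list alone), with Ctgf (0.48, SE 0.06) and Amotl2 (0.55, SE 0.08) rising; the adjusted p of 0.109 was 0.0362 without siCTL replicate 1 and 0.0401 without GSK126 replicate 3 (alternatives 0.0362 to 0.492).

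Imprinted genes numbered 7 higher and 2 lower of 15 (7 and 3 adjusted over the list alone). Mest was 8.02-fold higher, from 3.94 ± 0.169 to 31.6 ± 1.41 CPM, and the growth factor gene Igf2 rose by 0.59 (SE 0.07), Dlk1 by 0.88 (SE 0.19) and Ndn by 0.33 (SE 0.07). The adjusted p of 0.00254 was 0.0954 without GSK126 replicate 3 and 0.0623 with an estimated correlation (alternatives 0.00118 to 0.141). Other developmental transcription factors, many of them known Polycomb targets, numbered 12 and 4 of 42 (14 and 4 adjusted over the list alone), with the homeobox genes Msx1 (1.47, SE 0.26), Irx3 (0.74, SE 0.17) and Msx2 (0.51, SE 0.11) rising. Their adjusted p was 0.0297, and 0.286 with an estimated correlation (alternatives 0.00751 to 0.286). Hox genes, also Polycomb targets, numbered 1 higher, Hoxc13 (0.53, SE 0.07), and 6 lower of 21 (the same adjusted over the list alone; adjusted p = 0.434), among them Hoxa11 (-0.40, SE 0.07) and Hoxc6 (-0.56, SE 0.11). Of 12 PRC2 genes, 3 rose and 0 fell (the same adjusted over the list alone; adjusted p = 0.357), with the accessory subunit gene Phf19 at 1.21 (SE 0.14). PRC1 and demethylase genes numbered 3 and 1 of 18 (2 and 1 adjusted over the list alone; adjusted p = 0.994), with Phc2 at -0.22 (SE 0.06). Of those that rose, Bmi1 and Cbx6 were not past the threshold without siCTL replicate 3 (0.0648 and 0.0838), over alternatives from 0.000482 to 0.17 and 0.00752 to 0.103. Bmi1 lost its call when any 1 of 8 libraries was left out. Cadherin and catenin genes numbered 0 and 3 of 12 (the same adjusted over the list alone), with Jup at -0.37 (SE 0.08); the adjusted p of 0.103 was 0.0387 without GSK126 replicate 1 (alternatives 0.0387 to 0.557). The other 2, Cdh11 and Cdh13, were not past the threshold without siCTL replicate 3 (0.0557 and 0.0511, the highest of their alternatives, with 0.000108 and 0.00262 the lowest).

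Of the interferon and antigen-presentation genes, 5 of 32 rose and 0 fell (the same adjusted over the list alone). These 5 serve antigen presentation: the class I genes H2-K1 (1.11, SE 0.08) and H2-D1 (0.71, SE 0.07), Psmb9 (0.91, SE 0.13), B2m (0.31, SE 0.06) and Tap1. The adjusted p of 0.0297 was 0.0777 without siCTL replicate 1, 0.111 without GSK126 replicate 3 and 0.614 with an estimated correlation (alternatives 0.000634 to 0.614). Stress-response genes numbered 8 and 1 of 20 (10 and 1 adjusted over the list alone), with Asns at 0.52 (SE 0.07) and the cystine transporter gene Slc7a11 at -0.72 (SE 0.15). Their adjusted p was 0.0174, and 0.171 with an estimated correlation (alternatives 0.002 to 0.171). Cdk inhibitor, p53 and senescence genes numbered 8 and 2 of 21 (8 and 4 adjusted over the list alone), with Sesn1 at -0.45 (SE 0.06). Their adjusted p of 0.0585 passed the threshold without siCTL replicate 1, 2 or 3 (0.0184, 0.0314 and 0.0415) or siBcat replicate 1, 2 or 3 (0.0411, 0.0373 and 0.0311), over alternatives from 0.0184 to 0.208. In skeletal muscle genes 1 of 6 rose, Acta1 (2.10, SE 0.11; adjusted p of the list 0.0174; 0.282 without GSK126 replicate 3 and 0.171 with an estimated correlation; alternatives 0.00255 to 0.282). Of the haematopoietic markers 0 rose and 1, Cd14, fell of 8 (0 and 0 adjusted over the list alone). Cd14 was not past the threshold without GSK126 replicate 1 or 2 or siCTL replicate 1 or 2 (0.112, 0.0527, 0.134 and 0.0606; alternatives 0.00117 to 0.134). The test (adjusted p = 0.677) and the median of -0.16 pointed down and the mean of 0.14 up. No gene passed the threshold of edgeR in the endothelial (adjusted p = 0.677) and neural (adjusted p = 0.907) lists, over all genes or adjusted over the list alone; the smallest adjusted p there were 0.0878 for Egfl7, which was past it without siCTL replicate 2 (0.0142; alternatives 0.0142 to 0.259), and 0.108 for Tubb3.

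**Figure D4:**
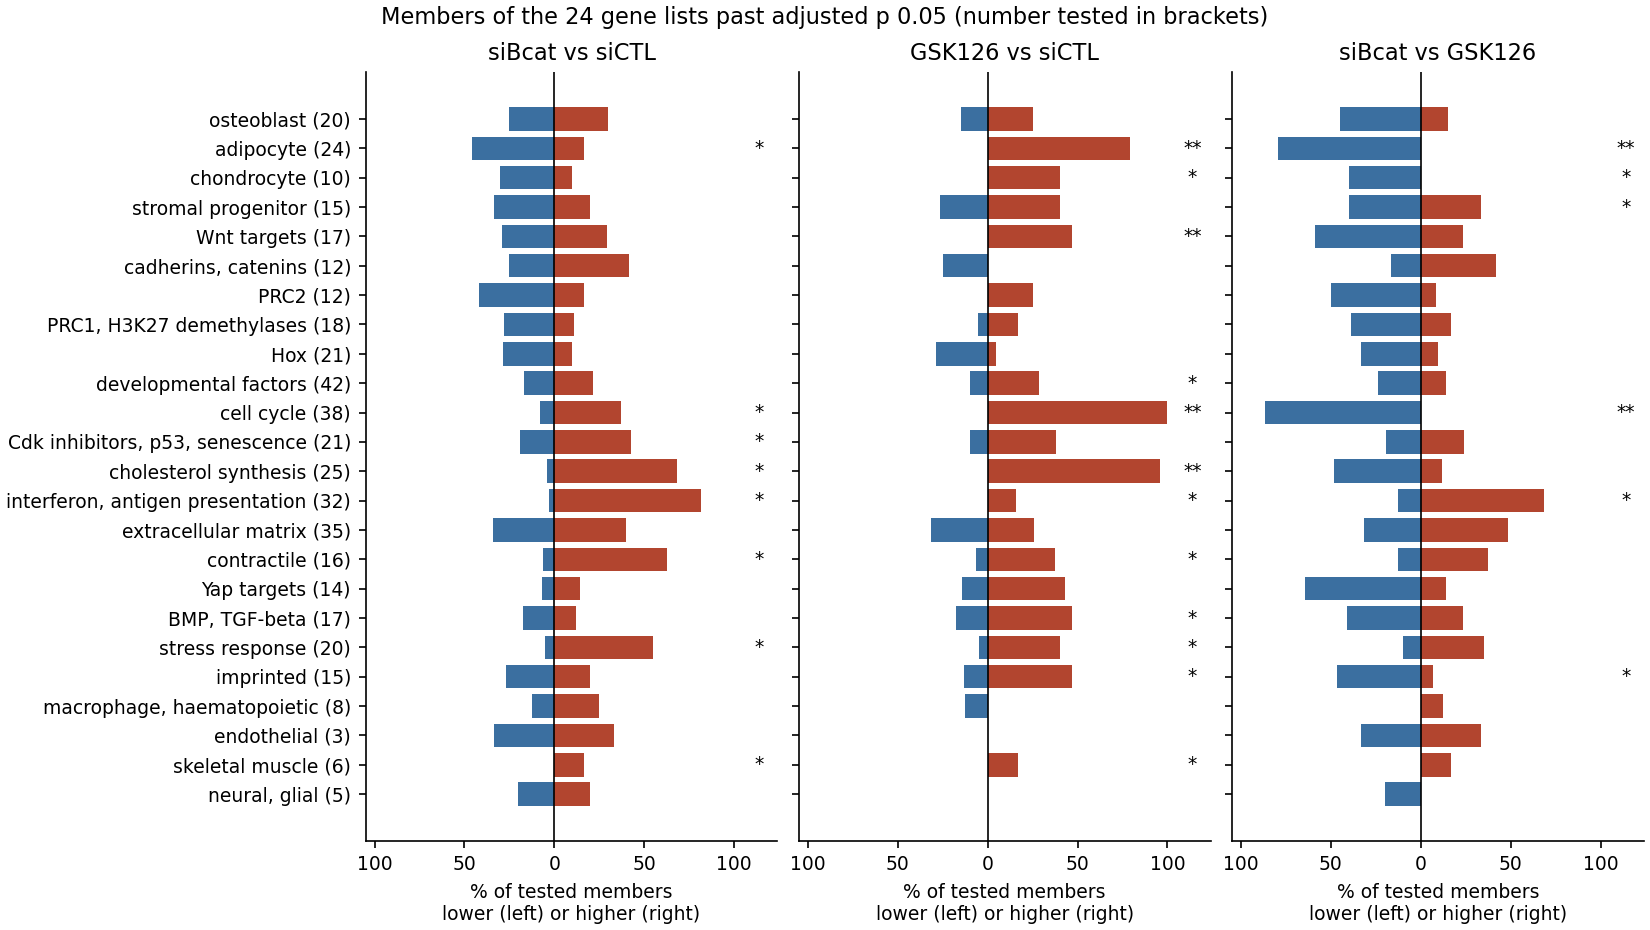
Share of the tested members of each of the 24 gene lists (number in brackets) that was higher (red, right) or lower (blue, left) at an adjusted p under 0.05, in percent, for each comparison; * marks lists past an adjusted p of 0.05 by camera with the preset correlation alone and ** those also past it with an estimated correlation. The 38 cell cycle genes all rose with GSK126, and 14 of them with siBcat.

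With GSK126, 1892 genes were higher and 1419 lower than in siCTL (25% of those tested), with 300 and 59 at a fold change of at least 2. The libraries of both groups did not overlap for 42.1% of the genes, against 10% by chance. Of the calls 57.1% were higher, a share of 66.1% with library size only, of 40.8% once the length trend was removed and of 41.6% once the GC trend was removed. Which direction held more genes thus turned with those 2 corrections. They also moved the median log2 fold change of all genes, from 0.006 to -0.043 and -0.033. An effect of length or GC content therefore cannot be told from a shift of scale. The list calls holding with an estimated correlation were cell cycle, adipocyte, cholesterol synthesis and Wnt targets.

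The comparison of siBcat with GSK126 tests the difference between both effects directly, since the control cancels. Adipocyte and cell cycle genes were lower in siBcat than in GSK126. Interferon-response genes were higher with the preset correlation only (adjusted p = 0.00106, and 0.604 with an estimated correlation). Of 24 adipocyte genes, 0 were higher and 19 lower (1 and 19 adjusted over the list alone): Adipoq was 24.5-fold lower (log2 fold change -4.62, SE 0.16, adjusted p = 8.93e-10), Cd36 29.6-fold (-4.89, SE 0.27), and Plin1 and Fabp4 differed by -4.76 (SE 0.22) and -1.97 (SE 0.09). Camera gave an adjusted p of 1.68e-27, and 0.000404 with an estimated correlation (alternatives 4.48e-36 to 0.000404). Of 38 cell cycle genes, 0 were higher and 33 lower (the same adjusted over the list alone), with the mitotic genes Ccna2 (-0.82, SE 0.06), Cenpf (-0.90, SE 0.07), Top2a (-0.64, SE 0.05) and Birc5 (-1.19, SE 0.10) among them (adjusted p = 7.35e-14, and 0.00116 with an estimated correlation; alternatives 4.6e-17 to 0.00116). With a mean of at least 2 CPM and no overlap between groups, the highest changes were Ifi44 (3.91, SE 0.62), Isg15 (3.06, SE 0.56), Oasl2 (2.74, SE 0.55), Usp18 (2.63, SE 0.44) and the kinesin gene Kif5c (2.58, SE 0.12). Besides the adipocyte genes the lowest were Ctnnb1 (-5.59, SE 0.05) and Sparcl1, at 0.140 CPM in siBcat and 4.92 CPM in GSK126.

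Interferon and antigen-presentation genes numbered 22 higher and 4 lower of 32 (the same adjusted over the list alone), with the class I gene H2-K1 (-0.66, SE 0.08) and Ifit2 (-0.50, SE 0.08) among the lower (alternatives 2.61e-07 to 0.604). Chondrocyte genes numbered 0 and 4 of 10 (the same adjusted over the list alone), with Col10a1 at -2.65 (SE 0.08) (adjusted p = 0.00245, and 0.393 with an estimated correlation; alternatives 0.000718 to 0.393). Imprinted genes numbered 1 and 7 of 15 (the same adjusted over the list alone), with Mest at -2.77 (SE 0.09) and Magel2 at -3.03 (SE 0.15) (adjusted p = 0.00634, and 0.13 with an estimated correlation; alternatives 0.00292 to 0.13). Stromal progenitor genes numbered 5 and 6 of 15 (6 and 6 adjusted over the list alone), with Cxcl12 at -1.74 (SE 0.05), Kitl at -1.41 (SE 0.08) and Vcam1 at -1.26 (SE 0.05). Their test pointed down (adjusted p = 0.0143; 0.263 without GSK126 replicate 3 and 0.393 with an estimated correlation; alternatives 0.0066 to 0.505), as did the mean of -0.26, with a median of 0.00.

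The other lists did not pass the threshold, but matrix genes did with the length trend removed (0.00629; alternatives 0.00629 to 0.671) or a filter of 1 CPM (0.0483), and contractile genes with the GC trend removed (0.0442; alternatives 0.0442 to 0.393). Wnt targets numbered 4 higher and 10 lower of 17 (adjusted p = 0.24), with Wisp2 at 1.41 (SE 0.07) and Nkd1 at -1.95 (SE 0.12). Osteoblast genes numbered 3 and 9 of 20 (adjusted p = 0.586), with Spp1 at 1.39 (SE 0.06) and Bmp2 at -2.81 (SE 0.28). Cholesterol synthesis genes numbered 3 and 12 of 25 (adjusted p = 0.212), with Hsd17b7 at 0.60 (SE 0.07). PRC2 genes numbered 1 and 6 of 12 (adjusted p = 0.207), with Phf19 at -1.87 (SE 0.14), and PRC1 and demethylase genes 3 and 7 of 18 (adjusted p = 0.212), with Cbx7 at -2.09 (SE 0.16). Hox genes numbered 2 and 7 of 21 (adjusted p = 0.27), with Hoxa10 at -0.66 (SE 0.05), and Yap targets 2 and 9 of 14 (adjusted p = 0.22), with Ctgf at -0.43 (SE 0.06). Matrix genes numbered 17 and 11 of 35, with Timp1 at 1.57 (SE 0.09) and Fbln1 at -1.93 (SE 0.07); their test (adjusted p = 0.188) and median (0.21) pointed up and their mean (-0.07) down. For contractile genes the counts were 6 and 2 of 16 (adjusted p = 0.151), for stress responses 7 and 2 of 20 (0.188), for BMP and TGF-beta genes 4 and 7 of 17 (0.24), for cadherins and catenins 5 and 2 of 12 (0.505) and for other developmental factors 6 and 10 of 42 (0.875). Cdk inhibitor, p53 and senescence genes numbered 5 and 4 of 21, with a test (adjusted p = 0.578) and median (0.02) pointing up and a mean of -0.02. The marker lists gave 1 and 0 of 8 for haematopoietic cells (adjusted p = 0.505), 1 and 1 of 3 for endothelium (0.835), 1 and 0 of 6 for skeletal muscle (0.578) and 0 and 1 of 5 for neural cells (0.98). The lower endothelial call, Vwf, was lost without GSK126 replicate 1 (0.144), siBcat replicate 1 or 2 (0.0902 and 0.115) or the GC trend (0.0571; alternatives 0.0167 to 0.144). The endothelial test pointed up with a median of -0.11 and a mean of 0.11, and the muscle test up with a median of 0.07 and a mean of -0.07. Adjusted over the list alone, the counts of these lists differed for matrix (18 and 11), contractile (7 and 2), Yap (3 and 9) and developmental genes (6 and 9).

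In all, 2549 genes were higher and 2901 lower in siBcat than in GSK126 (41.2% of those tested), with 239 and 558 at a fold change of at least 2, and the libraries of both groups did not overlap for 52.5% of the genes, against 10% by chance. Of the calls 46.8% were higher, a share of 33.4% with library size only, of 60% with the length trend removed and of 57.9% with the GC trend removed. The median log2 fold change of all genes moved as well, from -0.012 to -0.082, 0.053 and 0.043, so these shares may follow a shift of scale.

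The overlap of both treatments against siCTL asks which genes respond to both. Dio3, which inactivates thyroid hormone, rose by 2.86 (SE 0.24) with GSK126 and 2.64 (SE 0.25) with siBcat. The channel gene Kcnk3 (chromosome 5, 30588170 to 30625271) stood at 3.06 CPM in GSK126 and 0.479 CPM in siBcat, Ckmt1 at 0.565 and 0.868 CPM, and Ifi27l2a at 0.848 and 1.28 CPM. All 3 were past the threshold with both treatments, but lay under the floor of 0.129 to 0.135 CPM in siCTL, so no fold is given. Lower with both were Add2 (-2.29, SE 0.38 and -1.57, SE 0.36) and Susd2, at 24.1 CPM in siCTL against 7.39 CPM in GSK126 and 7.36 CPM in siBcat. Pde4b, which degrades cyclic AMP, rose with siBcat (1.15, SE 0.13) and fell with GSK126 (-0.95, SE 0.14), as did Tspan13 (0.99, SE 0.10, and -0.83, SE 0.10). The transporter gene Slc16a12 fell with siBcat (-1.86, SE 0.40) and rose with GSK126 (1.92, SE 0.28).

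**Figure D5:**
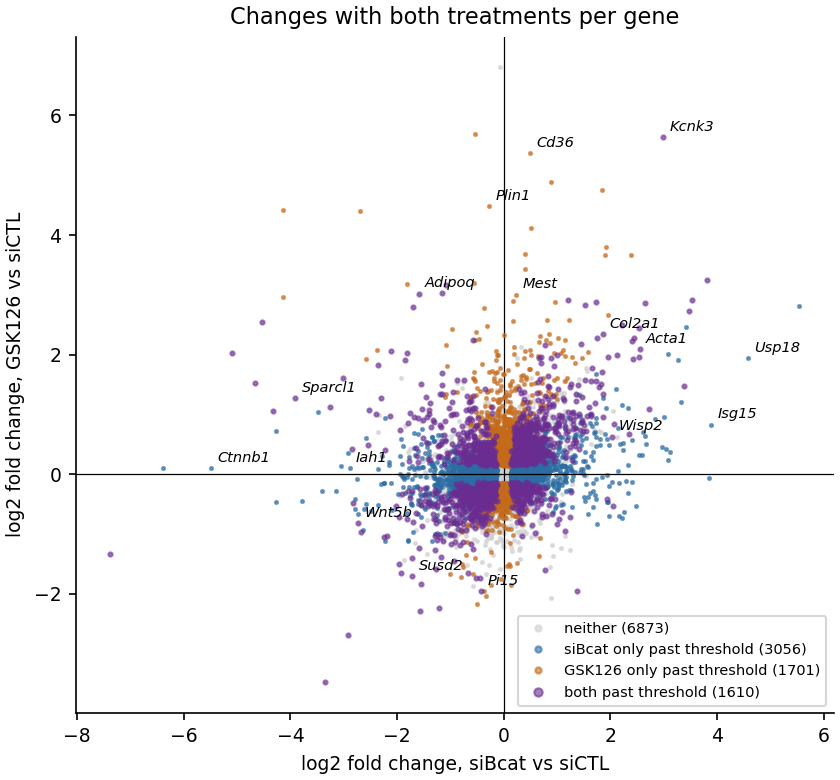
Log2 fold change with siBcat (horizontal axis) and with GSK126 (vertical axis), each against siCTL, of the 13240 genes tested (points), coloured by the comparison in which they passed an adjusted p of 0.05. Of 1610 genes past it in both, 581 were higher and 532 lower with both; both axes share the 3 siCTL libraries.

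Genes higher with both treatments numbered 581, where independent calls would give 335.2 (the product of both counts over the genes tested), and genes lower with both 532, where they would give 248.6. Opposite calls were fewer, with 200 genes higher with siBcat and lower with GSK126 (251.4 if independent) and 297 the other way (331.5). Because both comparisons use the same 3 siCTL libraries, groups without a change were simulated against shared controls, in 50 draws. They gave 0 genes called with both, a number that says little about real calls because such groups gave only 0.46 and 0.44 calls per comparison on average. They also gave a correlation of log2 fold changes across genes of 0.51 (0.472 to 0.533) against 0.242 observed, a same-sign share of 66.9% against 60.9%, and a covariance of 0.0218 (0.0196 to 0.0235) against 0.0574 observed. The correlation and the same-sign share are high by construction where all change is noise around the same controls. Real changes can lower both, so they do not measure the part owed to the controls. As 3 controls cannot be divided into parts of at least 2, part of the excess may come from the shared controls. Leaving out siCTL replicate 2 gave 369 genes higher and 367 lower with both and 104 and 188 with opposite calls; leaving out GSK126 replicate 3 gave 748, 814, 389 and 448.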

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

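Halved counts, the length and GC corrections and the families without GSK126 replicate 3 were chosen after the data were seen; the other alternatives were planned. A fold change of at least 2 left 265 genes higher and 338 lower with siBcat, 300 and 59 with GSK126, 239 and 558 in siBcat against GSK126, 46 and 21 higher and lower with both, 1 higher with siBcat and lower with GSK126, and 30 the other way. With the length trend removed, 2557 genes were lower with GSK126, 3981 higher in siBcat than GSK126, 810 lower with both, and 580 higher with siBcat and lower with GSK126. With the GC trend removed, 2294 were lower with GSK126 and 372 higher with siBcat and lower with GSK126, against 129 with library size only. Both corrections also moved the median log2 fold change of all genes, so these counts may follow a shift of scale. With 1 library left out, siBcat gave 1695 to 3202 genes higher and 1815 to 3118 lower, GSK126 1340 to 2029 and 988 to 1815, and siBcat against GSK126 2053 to 3061 and 2363 to 3257. Overlaps were lowest without siCTL replicate 2 and highest without GSK126 replicate 3: 369 to 748 higher with both, 367 to 814 lower with both, 104 to 389 higher with siBcat and lower with GSK126, and 188 to 448 the other way. The cause of these shifts was not tested. A replicate block gave 2278 genes higher and 2236 lower with siBcat, 1786 and 1349 with GSK126, and 2486 and 2781 in siBcat against GSK126, and deviations of libraries with the same number correlated at -0.031 to 0.069, so the numbers did not pair libraries. Of 335 gene results 302 kept their call in the alternatives run for them, as did 26 of 72 list results, and 0 changed direction while called. Among all gene results 152 entries were weaker and 3 stronger, and among list results 59 and 64. The fold change of at least 2 was applied to counts of genes only, and a gene lost to a stricter filter has no entry there. Depth limits genes near the floor of 0.107 to 0.142 CPM.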

Other observations

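The 26 families tested, of which only some are named below, and the comparison of control levels were chosen after the values were seen. So were all tests of explanations except the simulation with shared controls and the splits of the samples, which were planned before the data were examined; the bounds for judging every test were set after its value was known.

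With siBcat, 12 of 17 aminoacyl-tRNA synthetase genes, which load tRNAs with amino acids, rose and 1, Wars (-0.37, SE 0.05), fell; Gars rose by 0.42 (SE 0.06). Camera gave an adjusted p of 0.00705 for them, and 0.553 with an estimated correlation. Glutathione transferases numbered 2 higher and 6 lower of 12 (adjusted p = 0.00467, and 0.553 with an estimated correlation), with Gsta4 at -2.23 (SE 0.12), from 12.53 to 2.676 CPM, Gstt1 at -1.66 (SE 0.14) and Gstm1 at -1.20 (SE 0.07). Of 16 semaphorin genes, guidance cues, 10 fell and 1 rose (adjusted p = 0.00467, and 0.43 with an estimated correlation); Sema3f was at -1.52 (SE 0.16) and Sema7a at 0.73 (SE 0.05). Histone genes numbered 8 higher and 0 lower of 16 (adjusted p = 0.00337, and 0.274 with an estimated correlation), with Hist1h2bc at 1.34 (SE 0.10). Cytosolic ribosomal protein genes numbered 30 higher and 0 lower of 78 (adjusted p = 0.000843, and 0.696 with an estimated correlation), and 62 and 0 without GSK126 replicate 3 (7.1e-10). Between siBcat and GSK126, Wnt ligands, receptors and antagonists numbered 1 higher and 13 lower of 24 (adjusted p = 0.00227, and 0.481 with an estimated correlation), including Dkk2, Wnt5b and Fzd4. With GSK126, kinesin genes numbered 14 higher and 5 lower of 30 (adjusted p = 0.00489, and 0.903 with an estimated correlation), with the mitotic motors Kif11 (0.69, SE 0.07), Kif18b (0.76, SE 0.08) and Kif20a (0.52, SE 0.06) rising. Respiratory chain subunit genes numbered 36 higher and 0 lower of 80 (adjusted p = 8e-06, and 0.903 with an estimated correlation), and 29 and 2 without GSK126 replicate 3 (0.000455). Mitochondrial ribosomal protein genes numbered 17 and 0 of 76 (adjusted p = 0.00444, and 0.903 with an estimated correlation), and lost their call without that library (0.0784). Neither rise was particular to GSK126. With siBcat, respiratory chain genes numbered 14 and 1 (camera adjusted p = 0.0366) and mitochondrial ribosomal protein genes 17 and 2 (0.0395). Both were at 0.773 with an estimated correlation. No scaling turned the median of these families. Cytosolic ribosomal protein genes in GSK126 turned from 2 higher and 0 lower of 78 to 2 and 22 without GSK126 replicate 3.

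Genes that rose at least 2-fold with GSK126 had low levels in siCTL, with a median of 0.531 CPM and 63.3% under 1 CPM. Genes that rose at least 2-fold with siBcat were low there too, with a median of 0.817 CPM and 56.6% under 1 CPM. For those falling at least 2-fold with GSK126 the median was 1.56 CPM and the share 32.2%, and for all genes tested 24.5 CPM and 13.9%. These differences are partly built in. The filter by group admits genes near the floor in siCTL through a treated group alone, whereas a fall needs a measurable level in siCTL. Kcnk3, Cd36 and Plin1 were among the genes that rose with GSK126, all under 1 CPM in siCTL.

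Interferon-response genes were higher with siBcat, most in replicate 1, although the list test did not hold with an estimated correlation (adjusted p = 0.34). That library alone did not account for them, since 21 of 26 stayed past the threshold without it. The mean of all 32 genes tested also lay 1.02 and 1.07 (log2) above siCTL in replicates 2 and 3. All 26 had every siBcat library above every siCTL library, but being picked as past the threshold in these libraries favours that. Haematopoietic markers showed no matching gain. Together the 17 markers stood at 17.1, 15.2 and 14.8 CPM in siCTL and at 15.3, 14.7 and 15.4 CPM in siBcat. The largest gain of any 1 marker was 0.466 CPM, for Cd74. Together the 26 genes gained 495 CPM. These values argue against transcripts of haematopoietic cells as the source of the rise. The test on 17 markers replaced an earlier one on 6 of them. A response to the siRNA sequence itself could not be separated from loss of beta-catenin with 1 siRNA, and was not tested.

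GSK126 replicate 3 stood apart from its group. A trend on coding length took up 42% of the variance of its deviations, a value that may reflect RNA quality or library preparation. Neither was measured here. For RNA quality the labels give only minimums common to all 9 libraries: an RNA integrity number of 6 and a share of longer fragments (DV200) of 50%. Its changes were not smaller than those of its mates, as a mixture with untreated cells would make them: the slope on theirs was 0.992 (SE 0.022) over 127 genes, against 0.957 and 0.938 for the mates. The cell cycle genes did not depend on it, with 37 of 38 higher without it.

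More genes were called in the same direction with both treatments than independent calls would give. Against groups simulated without a change, the covariance of both log2 fold changes was higher by 0.0357 (0.0574 against at most 0.0235). The simulation gave each gene 1 level, pooled over all 9 libraries. Genes near the floor in siCTL alone, such as Kcnk3, were thus simulated with better-measured controls than they had. The simulated covariance may therefore be too low, and the gap does not decide whether the spread among the control libraries is its only source. The correlation (0.242 against 0.51) and the same-sign share (60.9% against 66.9%) were lower. Both are high by construction where all change is noise around the same controls, so they do not bear on the overlap. How much of the overlap comes from the shared controls stays open, since 3 controls cannot be divided. The label listing GSK126 for siBcat could also make both alike. The 300 genes at least 2-fold higher with GSK126 had a median log2 fold change of 0.284 in siBcat (quartiles -0.39 and 0.90, SD 1.33), and 220 of them were lower in siBcat than in GSK126, while the 59 genes at least 2-fold lower with GSK126 had medians of -1.49 there and -0.77 in siBcat. Both sets were picked in the same GSK126 libraries, and 63.3% of the higher genes lay under 1 CPM in siCTL. That choice favours smaller changes in siBcat. The higher genes thus do not by themselves exclude an equal action of the inhibitor in siBcat, and the lower ones leave room for a partial one. These values do not settle whether siBcat cultures received it. The count columns of siBcat are named as without the inhibitor, like those of siCTL, so the treatment label stands alone in listing it.

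In each comparison the true grouping was the only 1 of 10 splits of the 6 samples with as many genes called. The other splits gave at most 0 genes past the edgeR threshold, and at most 318, 632 and 785 at an unadjusted p under 0.05 in siBcat against siCTL, GSK126 against siCTL and siBcat against GSK126. The 10 splits are too few for a share under 0.05.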
